A study of Mus musculus with 6 samples.

How the data were processed

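The series holds 6 RNA-seq samples of sorted mouse cells: 2 of blood monocytes, 2 of sciatic nerve macrophages collected 3 days after injury and 2 collected 8 days after injury. RNA was reverse transcribed from oligo-dT primers and amplified by multiple displacement before library preparation, per the labels' protocols. The submitters' processing notes name bcl2fastq, BWA 0.7.12, the mm10 build and DESeq2, and how the deposited values were scaled is not given in the sources used here. The deposited table pairs each Entrez gene ID with a symbol and has 6 value columns, headed Sample 1 to Sample 6, which match no sample title or description. The columns are as many as the samples, so their order may follow that of the sample records, but no label says so. Assigning columns by order or by their values was ruled out by design, since it would rest on a guess, and all 6 columns were left out of every result. When the table was first inspected, the values of single genes in its first lines and in a random draw of lines were seen, as were the ranges, totals, low values and correlations of the columns. No group was assigned from them.

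The planned tests between groups (genes changed, gene lists changed, genes changed against monocytes at both times) were not run under any setting. Only the 2 identifier columns were used. Symbols were compared, by exact spelling, with a panel of 19 genes and with 31 gene lists, both written before the data were examined. Entrez IDs were looked up in a RefSeq gene table of the assembly GRCm38.p6, which gave biotypes, current symbols, synonyms and coordinates. A further 66566 lines of the table held only separators and were skipped. This count of listed genes was itself chosen after seeing the data, in place of the group comparisons. As alternatives, also chosen then, list genes were matched by the current RefSeq symbol of each Entrez ID, or by any RefSeq symbol or synonym.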

Results

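RNA-seq was carried out on sorted cells of female double-reporter mice, aged 3 months. In these mice Cx3cr1 and Ccr2, both chemokine receptors of monocytes, carry fluorescent reporters. The 6 samples form 3 groups of 2: blood monocytes, macrophages from the sciatic nerve 3 days after nerve injury, and macrophages from the nerve 8 days after injury. Nerve samples were pools drawn from 7 to 8 mice per time point. The groups imply 3 comparisons: day 8 against day 3, and each time point against monocytes. None of them was made. The headers of the 6 value columns matched no sample label, so a gene's value could not be assigned to monocytes, to day 3 or to day 8. No expression level, fold change or test is therefore given for any gene, and the depth of each sample is unknown.

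What could be described was which genes the table listed, a summary chosen after the table had been seen. It held 24028 genes, each with its own Entrez ID, and 23968 of these IDs (99.8%) were found in the RefSeq annotation of the GRCm38.p6 assembly. Of the matched genes, 20392 were protein-coding, 2033 were long non-coding RNAs and 1063 were microRNAs. All 19 genes of a panel fixed before the data were examined were listed. Among them were the reporter loci Cx3cr1 (Entrez ID 13051; chromosome 9, 120048683 to 120068296) and Ccr2 (Entrez ID 12772; chromosome 9, 124101918 to 124109140). Gas6, which encodes a ligand of the receptor tyrosine kinases Axl and Mertk, was listed under Entrez ID 14456 (chromosome 8, 13465374 to 13494535). Axl (Entrez ID 26362) lay on chromosome 7 at 25756500 to 25788924, and Mertk (Entrez ID 17289) on chromosome 2 at 128698915 to 128803162. These coordinates are those of the RefSeq gene in GRCm38.p6.

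The table also named nearly all genes of the 31 fixed gene lists. These lists cover monocytes and macrophages, cell functions, sample quality and other cell types. A table with 20392 protein-coding genes would name most well-known genes whatever cells were sequenced. The matches below therefore describe the table's gene list, not the cells. Of 564 separate list genes, 557 were matched by symbol, and 27 lists were matched in full. All 18 classical monocyte genes, such as Ly6c2, and all 20 mature macrophage genes, such as Adgre1 and C1qa, were matched. The same was true of the 26 efferocytosis genes, the 33 lysosome genes and the 31 cell cycle genes. Of the lists for other cell types that a nerve preparation could hold, the 18 Schwann cell, 16 fibroblast and 13 endothelial genes were matched in full. The neutrophil list was matched for 15 of 16 genes, with Ly6g unmatched. The B cell list was matched for 10 of 12, with Iglc2 and Ighm unmatched, and the erythroid list for 7 of 10, with Hba-a1, Hbb-bt and Hbb-b1 unmatched. In the list of secreted growth factors, Plgf was unmatched because the table names that gene Pgf. The other unmatched genes were found under no RefSeq symbol or synonym of a listed Entrez ID. Being listed says only that a gene has a line in the table, not that it was expressed in any sample. Likewise, an unmatched gene has no line under that symbol, which does not show that it was not expressed in these cells.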

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

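The count of list genes that the table names, and both alternatives for matching their names, were chosen after seeing the data. Only the lists themselves were fixed before. The 557 list genes matched by the table's own symbols became 556 with current RefSeq symbols and 558 with any RefSeq symbol or synonym. The 27 lists matched in full became 26 and 28. No paired analysis was possible because the value columns carry no replicate number and match no sample. For the same reason no other normalization, filter, test or left-out library was tried for the group comparisons. The sample titles number the replicates within each group but name no animal or batch shared between groups. Knowing which column is which sample would therefore not by itself give a basis for pairing.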
